A study of Xenopus laevis with 2 samples.

How the data were processed

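Gene expression was compared on 2-colour arrays between Xenopus laevis ectodermal explants in which an inducible XOct-25 was switched on and explants of the same injected embryos in which it was not. The series holds 2 samples, the independent experiments 1 and 2, which form 1 group. Each sample is a ratio of dexamethasone-treated to untreated explants as the labels describe it, so each experiment brings its own control. Per the labels' protocols, about 100 explants gave the total RNA of each sample, which was amplified with T7 RNA polymerase and labelled with Cy3 or Cy5 by random-primed reverse transcription. The number of experiments limits the precision of every value.

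The deposited table gives 1 value per clone and experiment. These values are log2 ratios made by the authors. The base of the logarithm was read from the values, since neither the table nor the labels state it. Raising 2 to the deposited value gave a ratio of whole numbers no larger than 8000, within 6e-10 on the log2 scale, for 98.0% of the values of experiment 1 and 97.8% of those of experiment 2. The same search succeeded for 4.17% and 4.91% of values when they were read as base 10 logarithms, for 2.16% and 2.58% when read as natural logarithms, and for 1.23% and 1.33% after each value was moved at random by up to 1e-05. In a test on 4000 simulated ratios, 100.0% of the known whole numbers were recovered in lowest terms. A value of this form comes from a single quotient of 2 whole numbers, which the mean of separate dye-swapped log ratios would not give. The labels name both dyes for each channel, and how the dye orientations entered a column is not given in the sources used here. The image software, background correction, normalization before the ratio and the rule behind empty values are not given in the sources used here either. Dye bias of single clones is therefore open.

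The direction of the deposited ratio is not stated in the table. It was taken as treated over untreated, which is likely because channel 1 is described as the treated sample and the sample description sets the treated against the untreated explants. If the ratio runs the other way, every "higher" and "lower" below changes places. The medians of the columns are not at 0 (-0.06 and -0.09), and the columns were used as deposited.

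The array holds 4608 clones, whose IDs follow the layout of 12 plates of 384 wells (16 rows by 24 well numbers), and which are called clones here for that reason. The table does not pair the IDs with genes, and 0 of the 4608 IDs matched a gene ID, symbol, synonym or accession among the 44456 genes of the RefSeq table for the assembly Xenopus_laevis_v10.1. Clones are therefore reported by ID, without gene names or genome positions. The 23 gene lists fixed beforehand (neural plate, epidermis, BMP targets, organizer, mesoderm, endoderm, glucocorticoid response, other cell types and housekeeping groups among them) could not be linked to any clone and were not tested. The tests per gene and per gene list that had been planned were left out for the same reason.

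Clones with a value in both experiments, 3664 in number, were tested with limma 3.58.1 in R 4.3.3. An intercept was fitted to the pair of log2 ratios and tested against 0 with moderated statistics (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all tested clones and a threshold of 0.05. Only 1 degree of freedom per clone measures the spread, so the test leans on the spread shared across clones. No intensities were used in this fit. The design, the alternatives and the rule for named clones were fixed before the data were examined. That rule takes, where IDs have no gene names, 2 clones per direction. None passed the threshold, so the clones named are those with the same sign in both experiments and the largest value of the smaller of their 2 absolute log2 ratios. Clones at least 2-fold changed the same way in both experiments were counted, and the count was set beside 10000 random re-pairings of the clones of experiment 1 with those of experiment 2.

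The recovered whole numbers were used as a measure of brightness. If they are the 2 channel signals, they are these signals divided by any common factor, so they bound each signal from below. Brightness is the mean log2 of the numerator and denominator, capped at the log2 of 8000 (12.97), the largest whole number taken as recovered. Values of exactly 0, 20 in experiment 1 and 30 in experiment 2, are recovered as 1 over 1. They were kept as ratios and count as dim whatever their signal. Recoveries under this limit can also arise by chance, as in the 1.23% and 1.33% of moved values above. The cap applied to 68 values of experiment 1 and 78 of experiment 2. Settings chosen after the values were seen use it as a filter (all 4 whole numbers of a clone at 30 or more, or at 100 or more), as a trend in the variance model, or as the x axis of a loess fit within each experiment. Another such setting subtracts the median of each well number within each experiment. With the filter at 100 or more, limma replaced each clone's own spread with 1 spread shared by all clones. On centred columns the same filter gave the shared spread 80.5 degrees of freedom, against 1 for the clone. The alternatives fixed beforehand were centring, scaling to one median absolute deviation, quantile normalization, a robust variance model, a test against a 1.2-fold minimum (treat), a filter on small values, a threshold of 0.10, a turned sign, and each experiment alone. The limma test was tested on simulated data for this comparison, in 20 draws of 3664 clones with the fitted spread, of which 200 clones were changed. It recovered 13.0% of the 1.5-fold, 80.7% of the 2-fold and 98.5% of the 4-fold changes at the 0.05 threshold, and 6.49% of its calls were false. The fit with a brightness trend, in a simulation of its own, recovered 63.8%, 90.8% and 98.4%, and 9.15% of its calls were false. Its noise was drawn from its own fitted spread, which varied with brightness, while the noise of the first simulation did not. The shares of the 2 fits are therefore not comparable. Changed clones were given the same true change in both experiments, and noise of the same size in both columns. The measured columns differ in spread, and the shares hold only for 200 changed clones. They do not tell how many real changes were missed. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.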

Results

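XOct-25 is a POU-domain transcription factor of the early frog embryo, in the family that also holds mammalian Oct4. To find transcripts that respond to it in ectoderm, embryos at the 8-cell stage received 1 ng of mRNA for XOct-25 fused to the hormone-binding part of the glucocorticoid receptor (GR), a fusion that stays inactive until dexamethasone is added. Ectoderm was cut out at stage 9, a blastula stage, and kept with or without 2 µM dexamethasone until siblings reached stage 10.5, an early gastrula stage. Treated and untreated explants carried the same injected mRNA, so a clone for XOct-25 itself could not check the labels. Dexamethasone-treated explants without the fusion are not analysed here, so responses to the hormone alone and to XOct-25 were measured together.

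Experiment 1 gave a log2 ratio for 3743 of the 4608 arrayed clones and experiment 2 for 3992. Values in both experiments were present for 3664 clones, in experiment 1 alone for 79, in experiment 2 alone for 328, and in neither for 537. The median log2 ratio of all clones with a value was -0.06 in experiment 1 and -0.09 in experiment 2. Over the 3664 shared clones the standard deviation across clones was 0.470 in experiment 1 and 0.216 in experiment 2. In experiment 1, 53 of the shared clones were at least 2-fold higher and 120 at least 2-fold lower with dexamethasone. In experiment 2 the counts were 2 higher and 19 lower.

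The first question was whether the same clones moved in both experiments. Across the 3664 shared clones the log2 ratios correlated with a Pearson r of 0.194 and a Spearman rho of 0.239, and 60.2% of clones had the same sign. These are correlations across clones, which are not independent replicates. Re-pairing the clones at random gave r between -0.032 and 0.032 in the central 95% of 10000 draws. The same draws gave 55.5% of clones with the same sign on average (54.2% to 56.8%), above an even split because both columns lean negative. With each column centred on its median the share was 58.4%, against 48.3% to 51.6% after re-pairing. The spread between experiments, taken as the standard deviation of the difference divided by the square root of 2, was 0.338 on the log2 scale. Agreement was closer among bright clones by r and by the spread, slightly by rho, and hardly by the share with the same sign (60.4%). In the 2623 clones, called bright clones below, whose recovered whole numbers were all at 100 or more, a filter chosen after the values were seen, r was 0.425, rho was 0.280 and the spread between experiments was 0.151. Without the 1% largest absolute values of these clones in each experiment, r was 0.308 and rho 0.253.

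**Figure D1:**
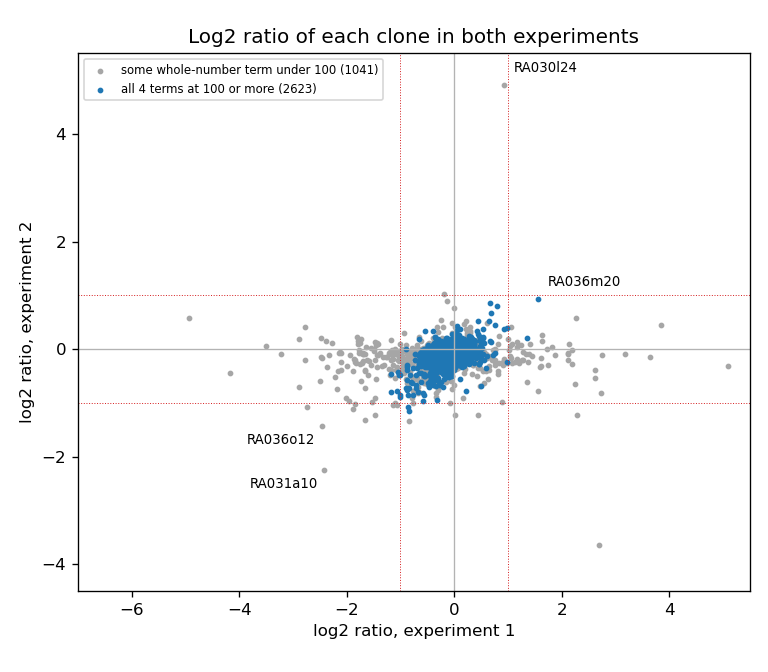
Log2 ratio of dexamethasone-treated over untreated explants in experiment 1 (x axis) and experiment 2 (y axis) for the 3664 clones measured in both, with 1 point per clone; blue points have all 4 recovered whole numbers at 100 or more (2623 clones) and grey points do not (1041 clones), and dotted lines mark 2-fold changes. The bright clones form a cloud with a weak upward tilt (r = 0.425, or 0.308 without their 1% largest absolute values), while most far points are grey, with RA036m20 the blue point farthest to the upper right.

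The second question was which clones changed with XOct-25 activation. Clones at least 2-fold lower in both experiments numbered 10, from 7 of the 12 plates, and clones at least 2-fold higher in both numbered 0. With each column centred on its median these counts were 5 lower and 1 higher. The 10 lower clones had a median mean log2 ratio of -1.46 (2.76-fold lower), with a median SD of 0.214 between the pair of experiments. All 10 were further from 0 in experiment 1, where their median was -1.76 (3.38-fold lower), than in experiment 2, where it was -1.09 (2.13-fold lower). Another 2 clones passed 2-fold in opposite directions. Random re-pairing gave 0.615 lower clones on average and at most 4. Re-pairing within 10 groups of like brightness gave 2.57 on average and at most 9. On centred columns, re-pairing within these groups gave 1.51 lower clones on average and at most 6, and 0.90% of draws reached the 5 observed. Of the 10 lower clones, 9 had a recovered whole number under 30 in at least 1 experiment.

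At a limit of 1.5-fold, 46 clones were lower and 5 higher in both experiments, and 8 passed the limit in opposite directions. A recovered whole number under 30 was present in 25 of the 46 lower and 1 of the 5 higher clones. After subtraction of well-number medians, 32 of the 46 and 4 of the 5 stayed past the limit in both experiments. Re-pairing within groups of like brightness gave 13.0 lower and 0.610 higher on average. Among the 2623 bright clones, 17 were lower and 4 higher in both experiments, with 0 in opposite directions. Re-pairing these bright clones gave 0.810 lower and 0.0277 higher on average, and at most 6 and 2. The 17 lower bright clones came from 7 plates and were 1.52-fold to 2.00-fold lower (median 1.76-fold, median SD 0.090 on the log2 scale). The 4 higher bright clones came from 3 plates and were 1.60-fold to 2.37-fold higher (median 1.72-fold, median SD 0.075).

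The test of each clone against 0 called 0 clones higher and 0 lower at an adjusted p of 0.05 (limma, Benjamini-Hochberg over 3664 clones; lowest adjusted p 0.110). At an unadjusted p under 0.05 the same test gave 28 higher and 289 lower clones, where 183 are expected by chance with no effect. With each column centred on its median these counts were 51 and 171. The share of higher clones was thus 8.83% as deposited, 23.0% after centring, which itself moves the balance, and 91.2% if the ratio runs the other way. With a robust variance model, limma called 3 clones higher and 38 lower at the same threshold, but on centred columns that model called 0 and 1. Restricting the fit to the 2623 bright clones and subtracting well-number medians gave 16 higher and 60 lower calls, a setting chosen after the values were seen.

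Of the clones with higher values, RA036m20 came first by the rule for named clones. Its log2 ratio was 1.55 in experiment 1 and 0.93 in experiment 2, a mean of 1.24 ± 0.44 (SD, n = 2), or 2.37-fold higher with dexamethasone (limma adjusted p = 0.273). Its ratios corresponded to 4240 over 1443 and 2821 over 1481, so it was bright in both experiments. RA030l24 came second, with log2 ratios of 0.93 and 4.91. Its mean of 2.92 ± 2.81 (SD, n = 2; limma adjusted p = 0.575) was close in size to its SD, and its ratios corresponded to 19 over 10 and 30 over 1.

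Among clones with lower values, RA031a10 had log2 ratios of -2.42 in experiment 1 and -2.25 in experiment 2. Its mean was -2.33 ± 0.12 (SD, n = 2), which is 5.03-fold lower with dexamethasone, and its limma adjusted p of 0.110 was the lowest of all clones. The ratios corresponded to 3 over 16 and 4 over 19, so both experiments read it at whole numbers under 30 unless a common factor was removed. RA036o12 had log2 ratios of -2.46 and -1.44, with a mean of -1.95 ± 0.72 (SD, n = 2; limma adjusted p = 0.270), which is 3.85-fold lower. Its ratios corresponded to 45 over 247 and 17 over 46.

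**Figure D2:**
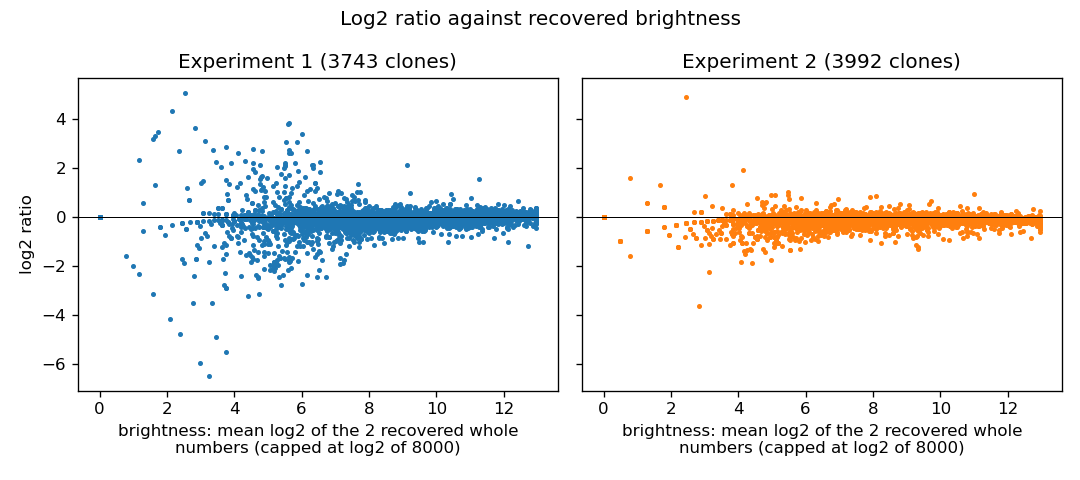
Log2 ratio (y axis) against brightness (x axis, mean log2 of the numerator and denominator recovered from the ratio, in lowest terms, capped at 12.97) for each clone with a value, 3743 clones in experiment 1 (left) and 3992 in experiment 2 (right). Ratios fan out toward low brightness in both experiments and more widely in experiment 1, whose values run from -6.52 to 5.09, against -3.64 to 4.91 in experiment 2.

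The size of the ratios depended on brightness. Of the shared clones, the dimmest of 10 equal groups had a standard deviation across clones of 1.098 in experiment 1 and 0.459 in experiment 2, and the brightest group had 0.188 and 0.131. The correlation between experiments was 0.106 in the dimmest group, 0.025 in the second, 0.174 in the third, and between 0.391 and 0.575 in each of the 7 brightest groups. Median ratios also followed the well number in the clone ID. In experiment 1 they ran from -0.23 at well number 11 to 0.08 at well number 18, and in experiment 2 from -0.20 at well number 13 to -0.01 at well number 24. Among the bright clones, well number accounted for 19.1% of the variance in experiment 1 and 18.9% in experiment 2, where 1000 permutations of the well numbers gave 97.5th percentiles of 1.46% and 1.45%. After the well-number medians were subtracted, 14 bright clones were at least 1.5-fold lower and 3 at least 1.5-fold higher in both experiments, and r among bright clones was 0.496.

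**Figure D3:**
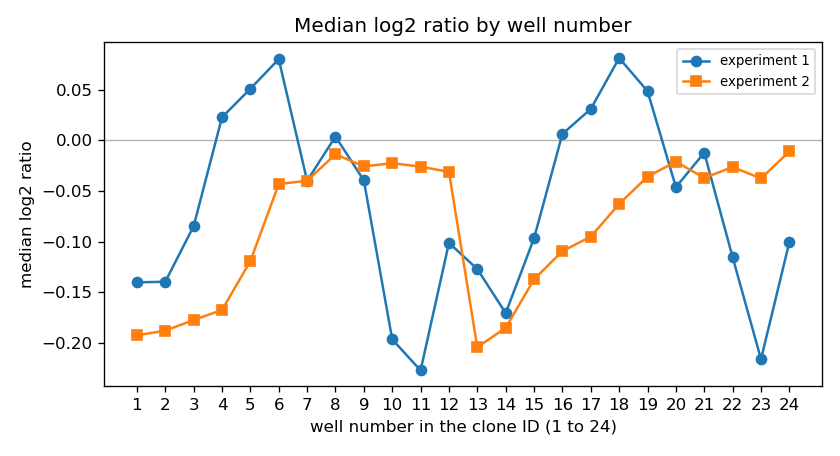
Median log2 ratio (y axis) of the 3664 shared clones by the well number in the clone ID (x axis, 1 to 24), with a line for each experiment. Each line repeats its shape from the first 12 well numbers to the next 12, and the line of experiment 1 peaks at well numbers 6 and 18 while that of experiment 2 is lowest at 1 and 13.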

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

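Counts of calls by limma depended on the variance model, on centring or well-number medians in some fits, and on which clones were tested. The settings that use brightness or well number, and the combined ones, were chosen after seeing the data. Centring, scaling, quantile normalization, treat, a threshold of 0.10, a turned sign, well-number medians, loess on brightness and a brightness trend on centred columns all left 0 calls. The other settings gave these higher and lower calls at an adjusted p of 0.05. The robust model gave 3 and 38, and 0 and 1 on centred columns. Leaving out the clones under 0.1 in both experiments gave 35 and 183, a filter on the outcome itself that removes the quiet clones. The brightness trend gave 2 and 16, and with the robust model 6 and 37, of which 27 were also among the 41 robust calls. In simulation 9.15% of brightness-trend calls were false, against 6.49% without the trend. The robust models were not simulated. Clones with all whole numbers at 30 or more gave 14 and 103, and at 100 or more 22 and 118, or 33 and 86 when also centred and 16 and 60 after subtraction of well-number medians. The fits giving 22 and 118, and 33 and 86, hardly used each clone's own spread, and RA036m20 passed both. The brightness filters test fewer clones and drop strongly changed clones with 1 dim channel. Apart from the turned sign, the counts at an unadjusted p under 0.05 ranged from 12 to 130 higher and from 105 to 420 lower. At 1.5-fold the counts changed the same way in both experiments were 5 higher and 46 lower, against 0 and 10 at 2-fold. Centring gave 1 higher and 5 lower at 2-fold, scaling 1 and 11, well-number medians 1 and 4 (0 and 11 when the column medians were kept), whole numbers at 30 or more 0 and 1, and at 100 or more 0 and 0. With 1 experiment alone, the 2-fold counts ranged from 2 to 53 higher and from 19 to 120 lower, the larger from experiment 1. Pearson r was 0.279 with whole numbers at 30 or more and 0.425 at 100 or more (0.308 without their 1% largest absolute values), and Spearman rho was 0.280 at 100 or more and 0.264 after subtraction of well-number medians. The cause of the changes was not tested except where stated. RA036m20 passed 0.05 in 6 of 17 other settings (mean log2 ratio 1.24 to 1.63), RA031a10 in 3 of 13 (-2.47 to -2.21), RA036o12 in 2 of 13 and RA030l24 in 1 of 13. All kept their sign, but they were picked by sign and size, so this is no test. The limma test has no value with 1 experiment (no residual degree of freedom). Each ratio pairs treated with untreated explants, so the test against 0 was already paired. Tests per gene and of gene lists were not run for want of gene names. Depth on these arrays is signal over background, and ratios of dim clones are the least certain.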

Other observations

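The tests below that use brightness or well number, and those of the spread of experiment 1, were chosen only after the values were seen. Clones with a value in only 1 experiment were dim and far from 0 more often than shared clones. The 79 clones of experiment 1 alone had a median larger whole number of 61.0, against 486 for shared clones, and 34 were at least 2-fold higher and 15 at least 2-fold lower. The 328 clones of experiment 2 alone had a median of 50.5, against 475 for shared clones, and 4 were at least 2-fold higher and 27 at least 2-fold lower. These clones have no replicate check.

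The 10 clones lower by 2-fold or more in both experiments form the first pattern; none was higher on the values as deposited, and 1 was after centring. Independent noise of dim spots would have to give as many after re-pairing within brightness groups, and no re-pairing of 10000 gave more than 9. On centred columns, which hold 5 such clones, 0.90% of re-pairings gave 5 or more. Both counts are larger than noise usually gives if it is alike within a group. The standard deviation of experiment 1 fell from 1.098 in the dimmest group to 0.684 in the next, so clones of a group may differ in noise. Noise of the dimmest spots therefore stays open. Of the well position, only the well number was examined, not the row or plate. Well-number medians ran only from -0.23 to 0.08 in experiment 1 and from -0.20 to -0.01 in experiment 2. Offsets of this size could at most carry a clone across the limit. When well-number medians were subtracted and the column medians kept, 9 of the 10 stayed past 2-fold, with the median of their mean log2 ratios at -1.42 against -1.46. Centring the columns left 5 of the 10 and subtracting well-number medians, which also centres them, left 4, with that median still at -1.34, so a small offset carries several of them across the limit. Signal near background stays open for 9 of the 10, of which 5 had a whole number under 30 in both experiments, 2 in experiment 1 alone and 2 in experiment 2 alone; only 1 had all whole numbers at 30 or more. A response to XOct-25 or to dexamethasone itself, and a dye effect of the single clone, remain possible and were not tested.

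The second pattern is the correlation of the experiments, which rises from 0.194 over all shared clones to 0.425 among bright ones. It did not rest on the well number (row and plate were not examined), since r over all shared clones was 0.199 after well-number medians were subtracted. A few extreme clones are not the whole of the correlation: without the 1% largest absolute values of each experiment r was 0.238 over all shared clones and 0.308 among bright ones. Most of the rise among bright clones thus went with these extreme values. Without them rho was 0.235 over all shared clones and 0.253 among bright ones. Re-paired clones stayed at or under 0.032 in 97.5% of draws, and at or under 0.069 when re-paired within brightness groups; re-paired bright clones stayed at or under 0.039. The well-number profiles of the experiments were themselves nearly unrelated (r = 0.115 over 24 well numbers), although each profile repeated between its first and next 12 numbers (r = 0.906 in experiment 1 and 0.950 in experiment 2). A reproducible response of transcripts to the treatment was not tested and stays open. The r of 0.308 shows that some agreement remained without the most changed bright clones, but not what gave it. A dye effect tied to the clone would give the same correlation if both experiments were labelled in the same orientation, and the sources used here do not settle that.

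The third pattern is the wider spread of experiment 1. Dimmer spots in experiment 1, as measured by the recovered whole numbers, do not account for all of it. At equal brightness its standard deviation was still 1.45 times that of experiment 2 in the median of 10 bins. Equal whole numbers need not mean equal signal over background in the 2 experiments. A single scale factor over all brightness groups does not either, because the ratio of standard deviations varied 2.55-fold over them, from 1.24 to 3.15. The excess was largest in the 3 dimmest groups, at 2.18 or more, which may point to noisier background subtraction in experiment 1, and this was not tested further. In all other groups the ratio ran only from 1.24 to 1.53. A single factor with added noise of dim clones in experiment 1 is therefore not excluded.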
